A study of Mus musculus with 11 samples.

How the data were processed

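The samples were 11 bulk RNA-seq libraries from the apex of C57BL/6 mouse hearts, with 4 libraries without irradiation (NR), 4 after standard (S-PRT) and 3 after FLASH proton radiotherapy (F-PRT). Groups and replicate numbers came from the sample titles, which number NR and S-PRT 1 to 4 and F-PRT 2 to 4. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, total RNA with an integrity number above 9 was turned into libraries with a poly(A) selection and directional kit. Whether reads were counted by strand is not given in the sources used here, so antisense and overlapping genes are uncertain. Per the submitters' processing notes, FastQC, cutadapt, STAR, RSEM and edgeR were used, with no versions, and both GRCm39 and mm10 are named as builds.

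The deposited values per gene and library were expected counts and TPM, per the file headers. RSEM shares ambiguous reads between genes with a model, so expected counts need not be whole. The deposited TPM, per the file headers, are divided by effective length and scaled to the same sum in each library. The deposited gene and effective lengths in bases are averages over isoforms weighted by estimated abundance, per the file headers. Each file held the same 55414 gene identifiers. Of these, 52081 matched a mouse gene name table by identifier without version and 3333 did not, the latter with 0.072% to 0.355% of the counts of a library. The annotation at hand was GENCODE M21 on GRCm38, which is not the release of the identifiers. It served only for the GC content of transcripts (99.8% of tested genes had a value) and no coordinates are given. Of 242 named genes, 180 had whole expected counts in every library, to within 1e-09 counts. Another 30, among them Hspa1a, Irs1, Loxl2, Myh7 and Atp2a2, had none, so part of their reads was shared with other genes and their values are uncertain. Each library had 20758170 to 40136578 expected counts, and no pair of libraries of a group was alike within counting noise.

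Choices of test, samples, gene lists, named genes and alternatives were fixed before the data were examined, except where an alternative is said to have been chosen after. Expected counts were rounded to whole numbers and genes filtered with filterByExpr (minimum count 10, minimum total 15), which left 14556 genes. Counts were scaled with TMM and all 11 libraries entered a single quasi-likelihood fit in edgeR 4.0.16 (R 4.3.3) with 8 residual degrees of freedom. Calls used a Benjamini-Hochberg adjusted p under 0.05 for S-PRT against NR, F-PRT against NR and F-PRT against S-PRT. A separate fit pooled the 7 irradiated libraries against NR on 14300 genes, so that the size of the response could be compared on genes chosen without the mode. That comparison used an exact two-sided permutation test over the 35 ways to name 3 of 7 libraries F-PRT. CPM values are TMM-scaled, log2 CPM used a prior count of 2, adjusted p values beside genes come from edgeR, and permutation tests are two-sided.

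In each comparison the text names the 10 genes with the largest increase and the 10 with the largest decrease among those called with a mean log2 CPM of at least 1, leaving out predicted genes, clone names and pseudogenes. If fewer than 3 passed in a direction, the 5 with the smallest p were taken, and up to 4 members of each list were added, or up to 2 with the smallest p where none passed. Some genes that this rule selects are not reported here. A fixed set of 19 genes was always looked up, of which Il6 fell below the count filter and 18 were tested. Of 42 gene lists, 37 had at least 5 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 37 lists. They were tested again with an estimated correlation and with fry, which tests whether a list's genes move in 1 direction on balance without comparing them with other genes. List scores are means over members of log2 CPM minus the NR mean.

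Replicate numbers were checked for pairing by correlating, between groups, each library's deviations from its group mean over 11107 genes. Between NR and S-PRT all 4 same-numbered pairs had correlations over 0.1 (0.18 to 0.36), so by the rule set beforehand these numbers pair the libraries. Of the 8 libraries, 3 were closest to their own number. Pairs within replicates 1 and 2 or within 3 and 4 had 0.17 to 0.44 against -0.45 to -0.20 for the others. The pairing comes from the data and the titles, as no label ties a number to an animal, day or batch.

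Comparisons with the same NR libraries were set beside 100 simulated draws of unchanged groups. The fits were tested on simulated data with 200 of 14556 genes changed. They recovered 49.3%, 70.1% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold in S-PRT against NR, and 29.9%, 74.6% and 84.8% in F-PRT against NR. Alternatives were size factors of DESeq2 1.42.0, library size only, removal of mitochondrially encoded genes, no filter or CPM of at least 1 in at least 3 libraries, and the DESeq2 Wald test. Others were limma on log2(TPM + 1), limma voom with quality weights, fits of only the groups compared, the replicate block, unrounded counts, and each library left out. Alternatives chosen after the data were seen were a robust dispersion, 1 surrogate variable (sva 3.50.0), removal of each library's trend on transcript length or on length and GC content, and fits of S-PRT and NR alone with the block or with replicates 1 and 2 against 3 and 4 as a term or apart.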

Results

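RNA from the apex of C57BL/6 mouse hearts was sequenced in bulk. There were 4 libraries without irradiation (NR), 4 after standard (S-PRT) and 3 after FLASH proton radiotherapy (F-PRT). FLASH delivers the dose at an ultra-high dose rate. The irradiated apexes received 40 Gy and were collected 2 weeks later. Expected counts per library summed to 28097280, 27780213, 31186064 and 37372372 in NR replicates 1 to 4. The sums were 27411007, 23655699, 33372893 and 40136578 in S-PRT replicates 1 to 4, and 23610573, 20758170 and 28571465 in F-PRT replicates 2 to 4. Of the 55414 gene identifiers, 14556 passed the count filter and were tested. Mitochondrially encoded transcripts took 37.0% ± 5.6 of the counts in NR, 41.2% ± 2.9 in S-PRT and 32.7% ± 9.1 in F-PRT (SD, n = 4, 4 and 3). Exact two-sided permutation p was 0.29 for S-PRT against NR, 0.49 for F-PRT against NR and 0.14 for F-PRT against S-PRT.

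Log2 CPM was centred per gene on its mean over the 11 libraries and correlated with transcript length across the genes of a library, which are not independent replicates. The Spearman correlation was 0.371 ± 0.034 in NR, -0.0257 ± 0.23 in S-PRT and -0.336 ± 0.20 in F-PRT (SD). It was lower than in NR after S-PRT (difference -0.397, exact permutation p = 0.029) and after F-PRT (difference -0.707, exact permutation p = 0.029). The irradiated groups differed by -0.31 (exact permutation p = 0.11). The values were 0.34, 0.37, 0.36 and 0.42 in NR replicates 1 to 4, and -0.26, -0.14, 0.03 and 0.27 in S-PRT replicates 1 to 4. In F-PRT replicates 2 to 4 they were -0.29, -0.16 and -0.56. After the group means were removed, the main axis of variation held 36.9% of the remaining variance and separated NR and S-PRT replicates 1 and 2 and F-PRT replicate 3 from the other 6 libraries.

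The comparison of S-PRT with NR asked which transcripts differed after irradiation at the standard dose rate. Cdkn1a (ENSMUSG00000023067.15), which encodes the p53-induced cell cycle inhibitor p21, rose from 7.96 ± 2.78 CPM in NR to 46.1 ± 23.1 CPM in S-PRT (SD, n = 4 each, log2 fold change 2.52 ± 0.35 SE, edgeR adjusted p = 0.007). Gdf15 (ENSMUSG00000038508.8), a secreted stress cytokine, rose from 0.59 ± 0.239 to 5.34 ± 3.8 CPM (3.14 ± 0.59, adjusted p = 0.028). Irf7, the transcription factor that drives type I interferon genes, rose from 6.97 ± 2.48 to 58.9 ± 38.3 CPM (3.07 ± 0.58, adjusted p = 0.031). Ccr2 (ENSMUSG00000049103.15), the chemokine receptor of recruited monocytes, rose from 1.89 ± 0.406 to 9.49 ± 3.5 CPM (2.33 ± 0.25, adjusted p = 0.0032). Cd163 (ENSMUSG00000008845.10), a scavenger receptor of resident macrophages, fell from 13.1 ± 2.29 to 4.67 ± 1.3 CPM (-1.51 ± 0.20, adjusted p = 0.0055). Cxcl12, a chemokine made by stromal and vascular cells, fell from 97.1 ± 10.8 to 41.6 ± 2.98 CPM (-1.22 ± 0.21, adjusted p = 0.021), with all 4 S-PRT libraries below all 4 NR libraries.

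Of 27 tested p53 response genes, 11 rose and 0 fell (19 and 0 when adjusted over the list alone). Camera called the p53 list higher (adjusted p = 1.9e-22, and adjusted p = 0.082 with an estimated correlation). The median log2 fold change was 0.75, and fry called it too (adjusted p = 0.011). Besides Cdkn1a and Gdf15, Phlda3, a p53-induced repressor of Akt, rose (1.68 ± 0.23, adjusted p = 0.007), as did Eda2r, a p53-induced death receptor (1.60 ± 0.25, adjusted p = 0.014). Mdm2, the ubiquitin ligase of p53, had a log2 fold change of 0.22 ± 0.09, adjusted p = 0.22. The mean p53 score per library was 0.84 ± 0.33 in S-PRT against 0 ± 0.15 in NR (SD of log2 values, n = 4 each, exact permutation p = 0.029, adjusted p = 0.098 over 37 lists). Among 30 cell cycle genes, 4 rose and 0 fell (23 and 0 when adjusted over the list alone). Among those that rose were the mitotic cyclin Ccnb1 (2.20 ± 0.46, adjusted p = 0.039), the spindle factor Tpx2 (1.82 ± 0.35, adjusted p = 0.031), the mitotic kinase Cdk1 (1.59 ± 0.32, adjusted p = 0.037) and the replication helicase subunit Mcm5 (1.24 ± 0.26, adjusted p = 0.039). Camera called the cell cycle list higher (adjusted p = 3.5e-19, and adjusted p = 0.39 with an estimated correlation, median log2 fold change 1.30). The proliferation marker Mki67 had a log2 fold change of 1.44 ± 0.34, adjusted p = 0.059. In the list of senescence and its secreted factors, 7 rose and 1 fell (10 and 2 when adjusted over the list alone) of 16 genes. The median log2 fold change was 1.49 and the list was called higher (adjusted p = 4.8e-07, and adjusted p = 0.39 with an estimated correlation). The genes that rose were Cdkn1a, Gdf15 and secreted factors of immune cells such as the monocyte chemokine Ccl8 (3.26 ± 0.59, adjusted p = 0.027) and the macrophage elastase Mmp12 (2.76 ± 0.56, adjusted p = 0.037). Igfbp3, which binds insulin-like growth factors, fell (-1.26 ± 0.23, adjusted p = 0.027). The apoptosis and necroptosis list was called higher with a median of 0.25 (adjusted p = 0.016, and adjusted p = 0.51 with an estimated correlation). No member passed the test over all genes, and 3 rose and 1 fell when adjusted over the list alone.

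All 27 tested type I interferon response genes had positive log2 fold changes after S-PRT, with a median of 1.53. Of these, 4 rose and 0 fell (22 and 0 when adjusted over the list alone), and camera called the list higher (adjusted p = 1.2e-21, and adjusted p = 0.39 with an estimated correlation). The antiviral GTPase Mx1 rose (3.78 ± 0.78, adjusted p = 0.037), as did Ifi27l2a (1.81 ± 0.28, adjusted p = 0.013) and Ifit1 (2.85 ± 0.60, adjusted p = 0.04). Ifit1 encodes an RNA-binding antiviral protein, and its expected counts were not whole in 9 of 11 libraries, so part of its reads was shared with other genes. The interferon score was 0.86, 0.87, 2.11 and 2.17 in S-PRT replicates 1 to 4 and -0.47, -0.47, 0.61 and 0.33 in NR replicates 1 to 4. The difference from NR did not pass over 37 lists (exact permutation p = 0.029, adjusted p = 0.098), and in both groups replicates 3 and 4 lay above 1 and 2 (not tested). Of 23 inflammatory cytokine and NF-kB genes, 4 rose and 0 fell (10 and 0 when adjusted over the list alone). These were the chemokines Cxcl10 (3.10 ± 0.67, adjusted p = 0.045) and Ccl2 (2.02 ± 0.40, adjusted p = 0.034), the cytokine Il1b (2.15 ± 0.35, adjusted p = 0.017) and the macrophage growth factor Csf1 (0.52 ± 0.11, adjusted p = 0.039). Camera called the cytokine list higher (adjusted p = 4.7e-07, and adjusted p = 0.46 with an estimated correlation), with a median log2 fold change of 0.84. Among 23 macrophage and monocyte markers, 3 rose and 1 fell (15 and 2 when adjusted over the list alone). Ccr2, galectin-3 (Lgals3, 2.04 ± 0.36, adjusted p = 0.026) and Aif1 (1.46 ± 0.29, adjusted p = 0.033) rose and Cd163 fell. Camera called the macrophage list higher (adjusted p = 3.1e-07, and adjusted p = 0.47 with an estimated correlation, median 0.79). All 17 antigen presentation genes had positive values (16 with library size scaling and 14 on log2(TPM + 1)). The list was called higher with no member past the test over all genes or over the list alone (median 0.65, adjusted p = 0.0011, and adjusted p = 0.63 with an estimated correlation). This call was lost without S-PRT 4 (adjusted p = 0.15) and with 1 surrogate variable (0.45). For complement, 0 rose and 0 fell (6 and 1 when adjusted over the list alone) of 17 genes (median 0.37, adjusted p = 0.004, and adjusted p = 0.6 with an estimated correlation). That call was lost without NR 2 (adjusted p = 0.17).

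Of 19 endothelial markers, 0 rose and 3 fell (0 and 6 when adjusted over the list alone). The ones that fell were the angiopoietin receptor Tek (-0.97 ± 0.17, adjusted p = 0.027), the vascular endothelial growth factor receptor Flt1 (-0.93 ± 0.18, adjusted p = 0.032) and the endothelial phosphatase Ptprb (-0.66 ± 0.08, adjusted p = 0.0048). Camera called the endothelial list lower (adjusted p = 2.2e-06, and adjusted p = 0.46 with an estimated correlation), with a median log2 fold change of -0.24. Ednrb, the endothelin B receptor, also fell (-0.98 ± 0.20, adjusted p = 0.036) together with Aqp7, a glycerol channel of capillaries and fat (-1.51 ± 0.32, adjusted p = 0.041). Nppb, which encodes brain natriuretic peptide, rose from 88.4 ± 18.6 to 165 ± 20.2 CPM (0.90 ± 0.17, adjusted p = 0.03). In the fetal and hypertrophy list, 1 rose and 0 fell (4 and 0 when adjusted over the list alone) of 13 genes, and the list had a median of 0.37 (adjusted p = 0.00012, and adjusted p = 0.39 with an estimated correlation). Fatty acid oxidation genes had negative log2 fold changes in 25 of 26 cases with a median of -0.25. Camera called the list lower (adjusted p = 7.3e-07, and adjusted p = 0.47 with an estimated correlation), but 0 members passed over all genes and 0 over the list alone. Sarcomere genes had a median of 0.02 and nuclear genes of oxidative phosphorylation a median of 0.08, and neither list was called (adjusted p = 0.95 and 0.3). The latter was called lower with the trend on transcript length removed (median -0.07, adjusted p = 0.001) and higher with 1 surrogate variable (0.00043) and without S-PRT 3 (0.026) or S-PRT 4 (0.024). The 13 mitochondrially encoded mRNAs were called higher with a median of 0.30 (adjusted p = 0.014, and adjusted p = 0.63 with an estimated correlation). The list had 0 members past the test over all genes or over the list alone, beside mitochondrial shares of 41.2% in S-PRT and 37.0% in NR.

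Col1a1 and Col3a1, the main fibrillar collagen genes, had log2 fold changes of 0.22 ± 0.33, adjusted p = 0.77 and 0.43 ± 0.32, adjusted p = 0.51. Postn, which encodes periostin of activated fibroblasts, had 1.21 ± 0.45, adjusted p = 0.18. Of 35 collagen and fibrotic matrix genes, 0 rose and 0 fell (2 and 1 when adjusted over the list alone). Camera called the list higher (adjusted p = 0.017, and adjusted p = 0.68 with an estimated correlation, median 0.28). The 12 activated fibroblast markers had a median of 0.50 and were called higher (adjusted p = 0.014, and adjusted p = 0.49 with an estimated correlation). Members past the test numbered 0 over all genes and 5 adjusted over the list alone. The 15 fibroblast identity markers had a median of -0.26 and were called lower (adjusted p = 0.01, and adjusted p = 0.63 with an estimated correlation). Members that fell numbered 0 over all genes and 2 adjusted over the list alone. Thbs2 and Thbs4, matricellular thrombospondins, had log2 fold changes of -1.01 ± 0.23, adjusted p = 0.055 and 1.01 ± 0.25, adjusted p = 0.071, and the protease inhibitor Timp1 had 1.69 ± 0.48, adjusted p = 0.1. Basement membrane genes (0.12), matrix proteases and their inhibitors (0.2) and TGF-beta signalling (0.65) were not called, these being camera adjusted p values, but were in 5, 4 and 1 of 23 other settings (lowest 1.3e-05, 0.012 and 0.047). The collagen call had adjusted p = 0.95 without NR 2, 0.46 without S-PRT 3 and 0.12 without S-PRT 4, and its direction turned to lower with 1 surrogate variable (0.25). The activated fibroblast call had 0.085 without S-PRT 3 and 0.08 with 1 surrogate variable, and the fibroblast identity call 0.096 without NR 4. The apoptosis call had adjusted p = 0.059 without S-PRT 3, 0.12 without S-PRT 4 and 0.24 with 1 surrogate variable, and the mitochondrially encoded call 0.052 without NR 3, 0.2 without NR 4, 0.11 without S-PRT 1 and 0.052 without S-PRT 2. With the trend on transcript length removed the mitochondrially encoded median was 0.14 (adjusted p = 0.29).

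Immediate early and handling stress genes were called higher (adjusted p = 4.9e-05, and adjusted p = 0.49 with an estimated correlation, median 0.60). Of the 17, 2 rose and 0 fell (7 and 0 when adjusted over the list alone), which were the heat shock gene Hspa1a (1.72 ± 0.36, adjusted p = 0.041) and the transcription factor Egr1 (1.68 ± 0.36, adjusted p = 0.045). In the NRF2 and antioxidant list, 1 rose and 0 fell (3 and 0 when adjusted over the list alone) of 18, and the glutathione peroxidase Gpx1 (0.65 ± 0.12, adjusted p = 0.027) passed. The list was called higher (adjusted p = 0.014, and adjusted p = 0.46 with an estimated correlation), but not with the trend on transcript length removed (median 0.09, adjusted p = 0.26) or with library size only (0.057). Its median of 0.14 became -0.01 with library size scaling and -0.05 on log2(TPM + 1). The integrated stress list was not called (adjusted p = 0.16, but 0.036 without S-PRT 2), and Sesn2, a stress-induced sestrin, rose (1.15 ± 0.23, adjusted p = 0.037). Calcium handling and ion channel genes were called lower (median -0.10, adjusted p = 0.027, and adjusted p = 0.64 with an estimated correlation) with 0 members past the test. It was not called with the trend on transcript length removed (adjusted p = 0.4) or with 1 surrogate variable (0.91), and adjusted p was 0.079 without NR 1, 0.25 without NR 2, 0.077 without S-PRT 3 and 0.14 without S-PRT 4. Glycolysis (adjusted p = 0.063, called in 6 of 23 other settings, lowest 0.021) and double-strand break repair (adjusted p = 0.34) were not called. Further genes with large increases were Bc1, a short non-coding RNA made by RNA polymerase III (2.37 ± 0.24, adjusted p = 0.0032), the histone gene Hist1h2ap (2.23 ± 0.30, adjusted p = 0.0066), Pcdhgc4 (3.01 ± 0.54, adjusted p = 0.026), Ifit3b (2.95 ± 0.59, adjusted p = 0.034) and Oasl1 (2.79 ± 0.59, adjusted p = 0.041). Expected counts were not whole in 11 of 11 libraries for Hist1h2ap and Ifit3b and in 10 for Pcdhgc4, so part of their reads was shared with other genes and these values are uncertain. Further genes with large decreases were the proteoglycan gene Spock2 (-1.40 ± 0.16, adjusted p = 0.0032), the transporter Abca4 (-1.36 ± 0.28, adjusted p = 0.037), the Ras exchange factor Rasgrf2 (-1.08 ± 0.21, adjusted p = 0.033), the cytochrome Cyp2d22 (-1.04 ± 0.21, adjusted p = 0.034) and Ahr, the aryl hydrocarbon receptor (-1.04 ± 0.20, adjusted p = 0.032). Of the 18 always-named genes tested, 3 passed and the other 15 had log2 fold changes from -0.18 for Atp2a2, the calcium pump of the sarcoplasmic reticulum, to 1.69 for Timp1.

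Across all genes, 188 of 14556 changed after S-PRT (127 higher and 61 lower, edgeR quasi-likelihood test). Of these, 92 changed at least 2-fold (77 higher and 15 lower). Camera called 22 of 37 lists (15 higher and 7 lower), 0 held with an estimated correlation, and fry called only p53 response. Replicate numbers paired the S-PRT and NR libraries, and a fit of these 8 with the replicate block called 1371 genes (903 higher and 468 lower) and 22 of 34 lists, with 0 lists held with an estimated correlation and 12 called by fry. That paired fit kept the calls of all 44 named genes that passed and added Mki67 (adjusted p = 0.00048), Thbs2 (0.0051), Timp1 (0.013), Postn (0.016) and Thbs4 (0.031). A block over the libraries of all 3 groups gave 60 genes and kept 18 of the 44. The count of 188 became 31, 44, 28 and 26 without NR replicates 1 to 4, 28 and 116 without S-PRT replicates 3 and 4, and 286 and 444 without F-PRT replicates 3 and 4. Of the 44, 8 (Bc1, Ccr2, Cd163, Cdkn1a, Hist1h2ap, Phlda3, Ptprb and Spock2) still passed without each library in turn, and none changed sign. Those that remained numbered 8, 13, 11 and 10 without NR replicates 1 to 4 and 33, 41, 9 and 17 without S-PRT replicates 1 to 4. With the trend on transcript length removed, 36 genes were called, 34 of them among the 188.

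**Figure D1:**
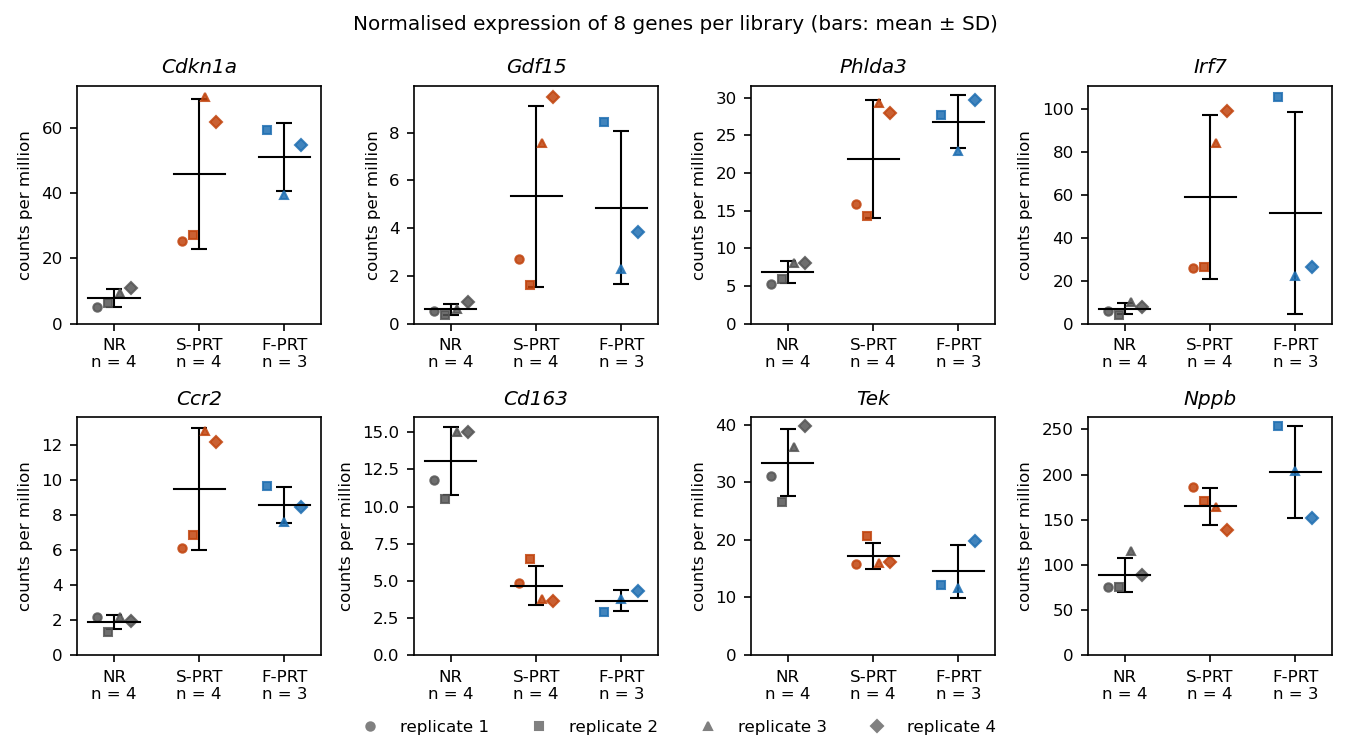
Expression of 8 genes in CPM, with 1 point per library and bars for the mean and SD of NR (n = 4), S-PRT (n = 4) and F-PRT (n = 3). Cdkn1a is near 8 CPM in NR and near 50 CPM in both irradiated groups.

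The comparison of F-PRT with NR asked the same question for irradiation at the FLASH dose rate. Cdkn1a rose from 7.96 ± 2.78 CPM in NR to 51.3 ± 10.4 CPM in F-PRT (SD, n = 4 and 3, log2 fold change 2.67 ± 0.36 SE, edgeR adjusted p = 0.0035). Ccr2 rose from 1.89 ± 0.406 to 8.59 ± 1.04 CPM (2.18 ± 0.27, adjusted p = 0.0024). Nppb, the brain natriuretic peptide gene, rose from 88.4 ± 18.6 to 203 ± 51.1 CPM (1.20 ± 0.18, adjusted p = 0.0046). Abca6 (ENSMUSG00000044749.14), a member of the lipid transporter family of ATP-binding cassette proteins, fell from 7.36 ± 1.41 to 1.92 ± 0.345 CPM (-1.96 ± 0.19, adjusted p = 0.00065). Cd163 fell from 13.1 ± 2.29 to 3.65 ± 0.709 CPM (-1.84 ± 0.22, adjusted p = 0.0022). Pdgfra, the growth factor receptor that marks fibroblasts, fell from 21.7 ± 6.46 to 8.49 ± 2.76 CPM (-1.34 ± 0.25, adjusted p = 0.0086).

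Of 27 p53 response genes, 16 rose and 1 fell (20 and 1 when adjusted over the list alone). Camera called the p53 list higher after F-PRT (adjusted p = 5.1e-12, and adjusted p = 0.32 with an estimated correlation, median log2 fold change 0.81), as did fry (adjusted p = 0.0057). Gdf15 (2.99 ± 0.62, adjusted p = 0.011), Psrc1 (2.49 ± 0.74, adjusted p = 0.034) and Phlda3 (1.97 ± 0.25, adjusted p = 0.0024) rose, and Mdm2 had a log2 fold change of 0.16 ± 0.10, adjusted p = 0.24. The p53 score was 0.88 ± 0.14 in F-PRT against 0 ± 0.15 in NR (SD, n = 3 and 4, exact permutation p = 0.029, the smallest that 35 splits allow, adjusted p = 0.15 over 37 lists). Of 30 cell cycle genes, 11 rose and 0 fell (17 and 0 when adjusted over the list alone). Among those that rose were the inhibitor of apoptosis and mitotic regulator Birc5 (1.99 ± 0.46, adjusted p = 0.015), Ccnb1 (1.72 ± 0.50, adjusted p = 0.033), the mitotic exit factor Cdc20 (1.64 ± 0.50, adjusted p = 0.038), the chromosomal passenger Cdca8 (1.60 ± 0.37, adjusted p = 0.016) and Mki67 (1.18 ± 0.37, adjusted p = 0.04). Camera called the cell cycle list higher after F-PRT (adjusted p = 2.6e-06, and adjusted p = 0.73 with an estimated correlation, median 1.11). The senescence list was called higher with a median of 1.09 (adjusted p = 0.021, and adjusted p = 0.73 with an estimated correlation). Of its 16 genes, 6 rose and 3 fell (8 and 4 when adjusted over the list alone), and adjusted p was 0.11 without F-PRT 2 and 0.16 without F-PRT 4. Ccl8 (3.10 ± 0.62, adjusted p = 0.01) and Mmp12 (2.83 ± 0.58, adjusted p = 0.011) were again among its members that rose. Double-strand break repair (adjusted p = 0.91) and apoptosis (adjusted p = 0.071, called higher in 7 of 20 other settings, lowest 0.012) were not called. Atm, the kinase that senses double-strand breaks, fell (-1.22 ± 0.31, adjusted p = 0.019).

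All 27 interferon response genes again had positive log2 fold changes, of which 10 rose and 0 fell (12 and 0 when adjusted over the list alone). Camera called the interferon list higher after F-PRT (adjusted p = 1.7e-06, and adjusted p = 0.73 with an estimated correlation, median 1.11). Mx1 (3.90 ± 0.81, adjusted p = 0.011), Irf7 (2.87 ± 0.60, adjusted p = 0.011) and the ubiquitin-like modifier Isg15 (2.24 ± 0.55, adjusted p = 0.018) rose. So did Ifit1 (2.49 ± 0.63, adjusted p = 0.019), Ifit3 (2.47 ± 0.61, adjusted p = 0.018), Ifit3b (2.84 ± 0.61, adjusted p = 0.012) and Oasl1 (2.62 ± 0.62, adjusted p = 0.017), of which the Ifit genes had reads shared with other genes. The interferon score was 2.13, 0.57 and 0.91 in F-PRT replicates 2 to 4 (exact permutation p = 0.086, adjusted p = 0.27 over 37 lists). Of 23 cytokine and NF-kB genes, 5 rose and 0 fell (6 and 0 when adjusted over the list alone). Cxcl10 (2.88 ± 0.71, adjusted p = 0.018), Ccl2 (1.89 ± 0.42, adjusted p = 0.014), Ccl7 (1.82 ± 0.44, adjusted p = 0.018) and Tnf (1.82 ± 0.50, adjusted p = 0.027) were among those that rose. The cytokine list was called higher (median 0.60, adjusted p = 0.016, and adjusted p = 0.73 with an estimated correlation), with adjusted p 0.09 without F-PRT 2, 0.064 without F-PRT 4 and 0.083 with 1 surrogate variable. Macrophage and monocyte markers were not called by camera (median 0.47, adjusted p = 0.059), but were called higher in 11 of 20 other settings (lowest 0.0068 without F-PRT 3). Of the 23 markers, 5 rose and 2 fell (6 and 2 when adjusted over the list alone). Ccr2 and Lgals3 (1.75 ± 0.38, adjusted p = 0.012) rose, and Cd163 and Timd4, markers of resident macrophages, fell (Timd4 -1.74 ± 0.46, adjusted p = 0.022). Antigen presentation (adjusted p = 0.057, called higher in 12 of 20 other settings, lowest 0.00097 without NR 3) and complement (adjusted p = 0.7) were not called. C7, a terminal complement component made by fibroblasts and mesothelium, fell (-1.74 ± 0.50, adjusted p = 0.031).

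Fibroblast identity markers had negative log2 fold changes in all 15 tested cases, with a median of -0.65. Of them, 0 rose and 4 fell (0 and 9 when adjusted over the list alone). These were the ferritin receptor Scara5 (-1.48 ± 0.28, adjusted p = 0.0089), Pdgfra, the actin regulator Gsn (-1.13 ± 0.32, adjusted p = 0.03) and the matrix protein Fbln1 (-0.65 ± 0.18, adjusted p = 0.029). Camera called the fibroblast identity list lower (adjusted p = 2e-05, and adjusted p = 0.73 with an estimated correlation). All 16 basement membrane genes had negative values (10 on log2(TPM + 1)) with a median of -0.47. Among them 0 rose and 6 fell (0 and 9 when adjusted over the list alone), such as the linker Nid1 (-1.0 ± 0.23, adjusted p = 0.015) and the collagen chain Col4a3 (-1.18 ± 0.37, adjusted p = 0.041). That list was called lower (adjusted p = 2.1e-05, and adjusted p = 0.73 with an estimated correlation). Its transcripts are long, with a median effective length of 5544 bases against 2270 over all genes. With the length trend removed its median was -0.14 (adjusted p = 0.08). TGF-beta signalling was called lower (median -0.14, adjusted p = 0.042, and adjusted p = 0.73 with an estimated correlation). Of its 26 genes, 0 rose and 7 fell (0 and 9 when adjusted over the list alone), with the co-receptor Tgfbr3 (-0.58 ± 0.09, adjusted p = 0.0053) and the latent binding protein Ltbp1 (-0.48 ± 0.13, adjusted p = 0.028) among them. Its median was 0.06 with the length trend removed (adjusted p = 0.9), and its adjusted p was 0.068 without NR 4, 0.19 without F-PRT 3 and 0.08 with library size only. Collagens and fibrotic matrix were not called (median -0.39, adjusted p = 0.054), but were called lower in 11 of 20 other settings (lowest 3.5e-08 with 1 surrogate variable), the block over all groups among them (0.0074). Col1a1 had a log2 fold change of -0.54 ± 0.36, adjusted p = 0.3, Col3a1 -0.33 ± 0.35, adjusted p = 0.53 and Postn 0.65 ± 0.48, adjusted p = 0.35. Thbs2 fell (-1.34 ± 0.26, adjusted p = 0.0096) and Thbs4 rose (0.85 ± 0.27, adjusted p = 0.046). Matrix proteases (adjusted p = 0.68) and activated fibroblast markers (adjusted p = 0.68) were not called.

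Endothelial markers were called lower (median -0.24, adjusted p = 0.016, and adjusted p = 0.73 with an estimated correlation). Of 19 tested, 1 rose and 3 fell (1 and 3 when adjusted over the list alone). Tek (-1.19 ± 0.19, adjusted p = 0.0054), Ptprb (-0.86 ± 0.09, adjusted p = 0.0011) and Flt1 (-0.82 ± 0.20, adjusted p = 0.017) fell and Egfl7, a secreted angiogenic factor, rose (0.73 ± 0.16, adjusted p = 0.013). That call had adjusted p = 0.37 without F-PRT 3 and 0.08 with the length trend removed. The fetal and hypertrophy list was called higher (median 0.85, adjusted p = 0.0042, and adjusted p = 0.73 with an estimated correlation). Of its 13 genes, 4 rose and 0 fell (4 and 0 when adjusted over the list alone), with Nppb and the stress-responsive ankyrin repeat gene Ankrd1 (1.19 ± 0.34, adjusted p = 0.029) among them. Adjusted p was 0.11 without F-PRT 2, and with the length trend removed the median was 0.56 (adjusted p = 0.0028). Myh7, the slow myosin heavy chain, had a log2 fold change of 1.28 ± 0.59, adjusted p = 0.14, and Atp2a2 had -0.55 ± 0.20, adjusted p = 0.07. Calcium handling and ion channel genes were called lower (median -0.21, adjusted p = 0.0011, and adjusted p = 0.73 with an estimated correlation). Of the 27, 0 rose and 5 fell (0 and 4 when adjusted over the list alone), with the calcium release channel Ryr2 (-0.86 ± 0.22, adjusted p = 0.022), the potassium channel Kcnd3 (-0.75 ± 0.18, adjusted p = 0.017) and the calcium channel subunit Cacna2d1 (-0.57 ± 0.14, adjusted p = 0.019) among them. With the length trend removed the median of that list was -0.14 (adjusted p = 0.08). For fatty acid oxidation, 0 rose and 4 fell (0 and 3 when adjusted over the list alone) of 26 (median -0.15, adjusted p = 0.02, and adjusted p = 0.73 with an estimated correlation). The lipid-sensing receptor Ppara (-1.51 ± 0.34, adjusted p = 0.014), Acsl1 (-0.60 ± 0.12, adjusted p = 0.011) and the fatty acid transporter Cd36 (-0.52 ± 0.13, adjusted p = 0.018) fell, and adjusted p of the list was 0.3 without F-PRT 2 and 0.15 with 1 surrogate variable. With the length trend removed its median was -0.24 (adjusted p = 5.4e-06).

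Nuclear genes of oxidative phosphorylation were called higher (median 0.30, adjusted p = 0.00057, and adjusted p = 0.73 with an estimated correlation). Of 31 genes, 8 rose and 0 fell (13 and 1 when adjusted over the list alone), including the complex I subunits Ndufa2 (0.68 ± 0.14, adjusted p = 0.011) and Ndufs7 (0.47 ± 0.14, adjusted p = 0.036). These transcripts are short, with a median effective length of 808 bases, and with the length trend removed their median was 0.01 (adjusted p = 0.54). Glycolysis was called higher (median 0.15, adjusted p = 0.042, and adjusted p = 0.73 with an estimated correlation), also by fry (adjusted p = 0.024). Of its 20 genes, 4 rose and 0 fell (5 and 0 when adjusted over the list alone). It was not called with the length trend removed (adjusted p = 0.33), and its camera adjusted p was 0.052 without NR 1, 0.065 without S-PRT 3, 0.12 without F-PRT 2, 0.16 without F-PRT 3, 0.054 with DESeq2 size factors and 0.055 with library size only. The 13 mitochondrially encoded mRNAs had a median of -0.18 and were not called (adjusted p = 0.27), but with the length trend removed they were called lower (median -0.41, adjusted p = 0.001), as without NR 4 (0.041) or F-PRT 3 (0.0021). Sarcomere genes were not called (adjusted p = 0.55), and troponin C (Tnnc1, 0.61 ± 0.12, adjusted p = 0.0094) rose while the thin filament protein Nebl fell (-0.64 ± 0.17, adjusted p = 0.025). The NRF2 and antioxidant (adjusted p = 0.078), integrated stress (adjusted p = 0.14) and immediate early lists (adjusted p = 0.19) were not called, but without F-PRT 3 they were called higher (0.026, 0.037 and 0.039), as was NRF2 without NR 3 (0.035). Members of the NRF2 and integrated stress lists that rose included the heme-degrading enzyme Hmox1 (0.96 ± 0.26, adjusted p = 0.026), Gpx1 (0.82 ± 0.13, adjusted p = 0.0046), the metallothionein Mt2 (1.05 ± 0.31, adjusted p = 0.035) and the stress transcription factor Ddit3 (1.05 ± 0.25, adjusted p = 0.016).

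The remaining genes with large changes were Rad9b (2.61 ± 0.60, adjusted p = 0.015) and Pcdhgc4 (4.63 ± 0.55, adjusted p = 0.0022), which rose. Those that fell were Nt5c1a (-1.98 ± 0.57, adjusted p = 0.031), Nr2c2 (-1.82 ± 0.36, adjusted p = 0.0097), Tgtp1 (-1.68 ± 0.53, adjusted p = 0.042), Adnp (-1.65 ± 0.52, adjusted p = 0.042), Pdpr (-1.64 ± 0.38, adjusted p = 0.016) and Pakap (-1.62 ± 0.35, adjusted p = 0.012). Rad9b, Pcdhgc4, Nr2c2, Tgtp1, Adnp and Pakap are uncertain, because their expected counts were not whole in at least 9 of 11 libraries and part of their reads was shared with other genes. Rad9b was at 23.2 CPM in F-PRT replicate 4 and at 3.34 and 2.78 CPM in replicates 2 and 3, and without replicate 4 it did not pass (log2 fold change 0.92, edgeR adjusted p = 0.083). Adnp was at 0.374 CPM in F-PRT replicate 4 and at 3.46 and 5.06 CPM in replicates 2 and 3. Adnp (adjusted p = 0.074) and Nt5c1a (0.091) did not pass without F-PRT replicate 2, nor did Tgtp1 without replicates 2 (0.073), 3 (0.089) or 4 (0.12). Lcor, a corepressor of nuclear receptors, also fell (-1.70 ± 0.23, adjusted p = 0.0035). Of the 18 always-named genes tested, 5 passed and the other 13 had log2 fold changes from -0.55 for Atp2a2 to 1.45 for Timp1. Across all genes, 2841 of 14556 changed after F-PRT (1579 higher and 1262 lower, edgeR quasi-likelihood test). More were lower than higher with DESeq2 size factors (1355 higher and 1391 lower), the CPM filter (1309 and 1493), the DESeq2 Wald test (1625 and 1761), and without S-PRT 3 (1164 and 1335) or F-PRT 4 (680 and 702). Of the 2841, 438 changed at least 2-fold (270 higher and 168 lower). Camera called 14 of 37 lists (8 higher and 6 lower), 0 held with an estimated correlation, and fry called p53 response, glycolysis and atrial markers. Genes that rose had a median effective length of 975 bases and genes that fell 4335. With the length trend removed 587 genes were called, 454 of them among the 2841. The count was 1408, 1651, 1695 and 1655 without NR replicates 1 to 4, 1773 without F-PRT replicate 2 and 1382 without F-PRT replicate 4. Of the 68 named genes that passed, 32 still passed without each library in turn and none changed sign. Those that remained numbered 47, 51, 56 and 51 without NR replicates 1 to 4 and 40, 63 and 46 without F-PRT replicates 2 to 4.

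The comparison of F-PRT with S-PRT asked whether the dose rate changed the response to the same dose. Collagen and fibrotic matrix genes had lower values in F-PRT than in S-PRT in all 35 tested cases, with a median log2 fold change of -0.63 (33 cases with library size scaling and 30 on log2(TPM + 1)). Camera called the collagen list lower (adjusted p = 3.4e-08, and adjusted p = 0.88 with an estimated correlation), while no member passed over all genes or when adjusted over the list alone. Log2 fold changes were -0.77 ± 0.37, adjusted p = 0.33 for Col1a1, -0.76 ± 0.35, adjusted p = 0.32 for Col3a1, -0.83 ± 0.29, adjusted p = 0.22 for fibrillin-1 (Fbn1), -0.95 ± 0.33, adjusted p = 0.23 for the collagen crosslinking enzyme Loxl2 and -0.56 ± 0.48, adjusted p = 0.59 for Postn (± SE, n = 3 and 4, edgeR). For the p53 response the median log2 fold change between the irradiated groups was 0.00 and their scores differed by 0.04 (camera adjusted p = 0.56, exact permutation p = 0.91, adjusted p = 0.99 over 37 lists). No gene passed the edgeR quasi-likelihood test (smallest adjusted p = 0.0517), while 2315 had an unadjusted p under 0.05. The DESeq2 Wald test called 167 genes, limma on log2(TPM + 1) 9 and limma voom with quality weights 0. Without F-PRT replicate 3, 103 genes passed.

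The genes nearest the threshold with lower values in F-PRT were Tmtc3, a membrane O-mannosyltransferase (-0.71 ± 0.10, adjusted p = 0.052), Irs1, an adaptor of the insulin receptor (-1.32 ± 0.22, adjusted p = 0.13), Abca6 (-1.08 ± 0.19, adjusted p = 0.15), Rasal2 (-0.56 ± 0.10, adjusted p = 0.15) and the sarcoglycan Sgcd (-0.85 ± 0.16, adjusted p = 0.15). Those with higher values were Hdgfl2 (0.47 ± 0.08, adjusted p = 0.15), the growth arrest gene Gadd45g (1.02 ± 0.20, adjusted p = 0.15), the cold-inducible RNA-binding protein gene Cirbp (0.49 ± 0.10, adjusted p = 0.17) and the splicing factor Rbm25 (0.47 ± 0.10, adjusted p = 0.17). In libraries simulated for this comparison, 28.4%, 68.7% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold were recovered. The collagen score per library was -0.26 ± 0.43 in F-PRT, 0.29 ± 0.50 in S-PRT and 0 ± 0.54 in NR (SD, n = 3, 4 and 4). F-PRT differed from S-PRT by -0.54 (exact permutation p = 0.29, adjusted p = 0.88 over 37 lists). Basement membrane genes were called lower (median -0.41, adjusted p = 2.1e-06, and adjusted p = 0.88 with an estimated correlation). The list had 0 members past the test over all genes and 7 adjusted over the list alone. The laminin gene Lama2 had -0.50 ± 0.10, adjusted p = 0.15. Their median was -0.19 with the length trend removed (adjusted p = 0.018) and 0.04 on log2(TPM + 1), where the median of all genes was 0.126. All 15 fibroblast identity markers had negative values (13 with library size scaling) and the list was called lower (median -0.39, adjusted p = 9.9e-05, and adjusted p = 0.88 with an estimated correlation). It had 0 members past either threshold, and adjusted p was 0.25 without F-PRT 3. Ccdc80 had a log2 fold change of -0.64 ± 0.29, adjusted p = 0.31 and Pdgfra -0.50 ± 0.25, adjusted p = 0.33. Complement was called lower (median -0.30, adjusted p = 0.039, and adjusted p = 0.88 with an estimated correlation). There were 0 members past either threshold, and adjusted p was 0.52 without S-PRT 3, 0.051 without S-PRT 4, 0.91 without F-PRT 3 and 0.067 with the stricter filter on CPM. C3, the central complement component, had a log2 fold change of -1.08 ± 0.38, adjusted p = 0.23.

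TGF-beta signalling genes were called lower in F-PRT than in S-PRT (median -0.18, adjusted p = 0.01, and adjusted p = 0.88 with an estimated correlation). There were 0 members past the test over all genes and 1 higher and 2 lower adjusted over the list alone. Tgfbr3 was at -0.39 ± 0.09, adjusted p = 0.18. The median was 0.01 with library size scaling and 0.05 on log2(TPM + 1). The call was not made with the length trend removed (adjusted p = 0.47). Adjusted p was 0.15 without S-PRT 3 and 0.25 without F-PRT 3. Calcium handling genes were called lower (median -0.16, adjusted p = 0.01, and adjusted p = 0.88 with an estimated correlation). There were 0 members past the test over all genes and 3 adjusted over the list alone. That median was 0 with library size scaling and 0.05 on log2(TPM + 1). The call was not made with the length trend removed (adjusted p = 0.13). Adjusted p was 0.11 without S-PRT 1, 0.14 without F-PRT 2 and 0.17 without F-PRT 4. Nuclear genes of oxidative phosphorylation were called higher (median 0.19, adjusted p = 2.7e-05, and adjusted p = 0.88 with an estimated correlation), with 0 members past either threshold. Examples were Ndufv1 (0.39 ± 0.11, adjusted p = 0.18) and Cox4i1 (0.37 ± 0.14, adjusted p = 0.25). With the length trend removed that median was 0.09 (adjusted p = 0.034). Mitochondrially encoded mRNAs were called lower (median -0.47, adjusted p = 3e-05, and adjusted p = 0.88 with an estimated correlation). There were 2 members past the test adjusted over the list alone, beside mitochondrial shares of 32.7% in F-PRT and 41.2% in S-PRT. The overlapping genes mt-Nd4l, with reads shared with other genes, and mt-Atp8 had -1.26 ± 0.35, adjusted p = 0.18 and -0.99 ± 0.28, adjusted p = 0.18.

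Medians were -0.27 for the interferon response (camera adjusted p = 0.09) and -0.26 for macrophage markers (0.056). They were -0.12 for cytokines and NF-kB (0.38) and -0.24 for the cell cycle (0.26), and none of these lists was called. In other settings the interferon response was called lower in 8 of 20 (lowest adjusted p = 3.2e-07 without F-PRT 2) and macrophage markers in 12 (0.0018 without F-PRT 2), the block over all groups among them (0.0044 and 0.0082). The cell cycle was called lower with library size only (0.009) and without S-PRT 1 (0.01), S-PRT 2 (0.022) or F-PRT 2 (0.014), and cytokines without S-PRT 2 (0.029) or F-PRT 4 (0.033). Il1b had a log2 fold change of -1.40 ± 0.37, adjusted p = 0.18 and the integrin Itgam, a marker of myeloid cells, -0.76 ± 0.25, adjusted p = 0.21. Nppb had 0.30 ± 0.18, adjusted p = 0.43 and Myh7 1.35 ± 0.59, adjusted p = 0.3, and the 18 always-named genes ranged from -0.77 for Col1a1 to 1.35 for Myh7 with 0 passing. Camera called 8 of 37 lists (1 higher and 7 lower), 0 held with an estimated correlation and fry called 0. Camera called 17 lists without S-PRT replicate 2, 5 without F-PRT replicate 3 and 20 without F-PRT replicate 4.

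**Figure D2:**
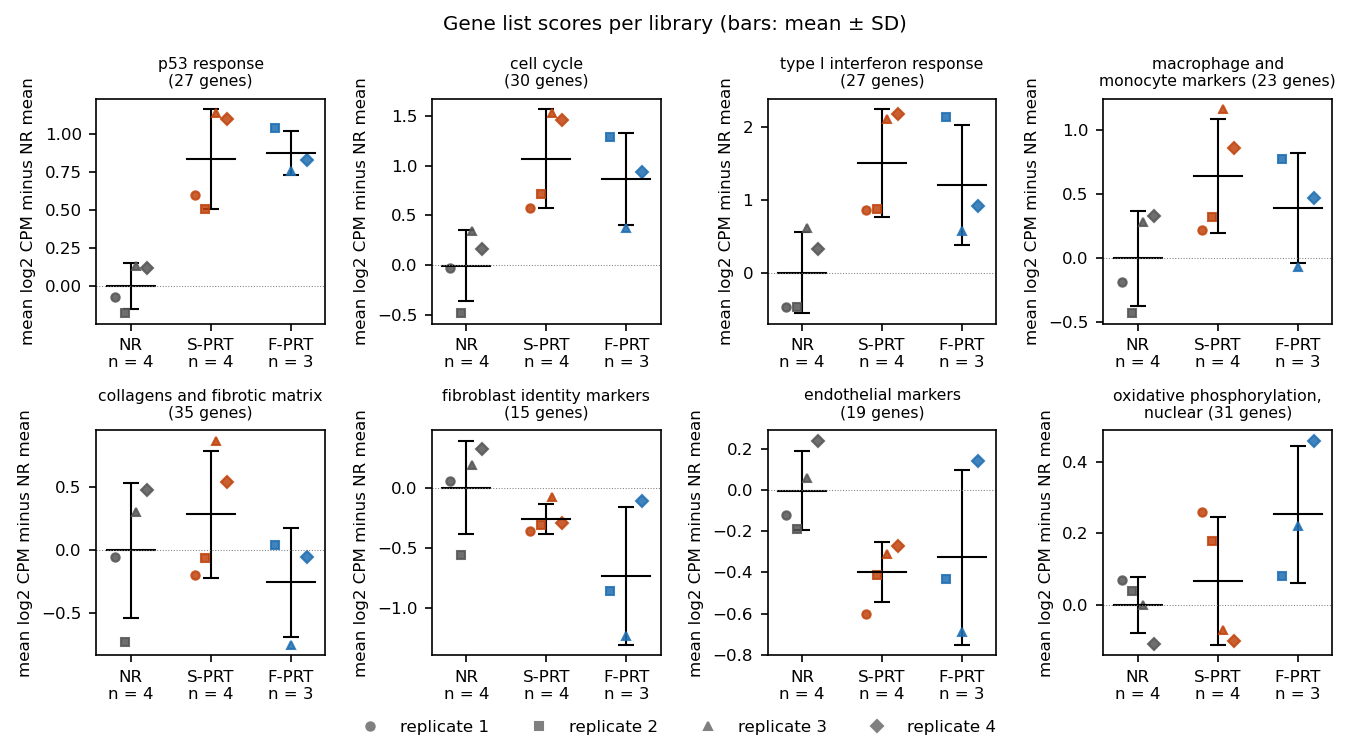
Scores of 8 gene lists per library, as the mean log2 CPM of the list's tested genes minus the NR mean, with bars for the group mean and SD (n = 4, 4 and 3). The p53 score lies above every NR library in all 7 irradiated libraries, and the collagen scores of the 3 groups overlap.

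The responses were then compared on genes chosen without regard to the mode. With S-PRT and F-PRT pooled as 7 irradiated libraries, 1000 of 14300 genes differed from the 4 NR libraries (620 higher and 380 lower, edgeR quasi-likelihood test). Over these 1000 genes, the mean log2 change in the direction of irradiation was 0.710 ± 0.108 in S-PRT and 0.822 ± 0.164 in F-PRT (SD, n = 4 and 3). The difference was 0.112 (exact permutation p = 0.314, smallest possible 0.029 with 35 splits). It was 0.104 for the 620 higher genes (exact permutation p = 0.571) and 0.126 for the 380 lower genes (exact permutation p = 0.114). Values were 0.67, 0.60, 0.86 and 0.71 in S-PRT replicates 1 to 4 and 0.98, 0.65 and 0.84 in F-PRT replicates 2 to 4. Without F-PRT replicate 2 the difference was -0.001. The count of 1000 was 188, 255, 254 and 186 without NR replicates 1 to 4, 1584 without S-PRT replicate 4 and 402 without F-PRT replicate 2.

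Across 14556 genes, which are not independent replicates, log2 fold changes against NR had r = 0.734 between S-PRT and F-PRT. Simulated unchanged groups with a shared NR gave 0.450 (0.405 to 0.481 in 100 draws). With the NR libraries divided between the comparisons r was 0.498 to 0.593. Covariance was 0.146 (0.0294 simulated, difference 0.117) and 0.114 to 0.129 with NR divided. Both sets of fold changes fall with transcript length, so the excess over the simulation need not go beyond that trend. Both comparisons called 174 genes in the same direction and 0 in opposite directions. The 174 were 119 higher and 55 lower (13.8 and 5.3 for independent lists). Simulated groups overlapped in 0, having at most 2 calls each, with the same limit. The overlap was 31, 43, 28 and 26 without NR replicates 1 to 4 and 27 and 110 without S-PRT replicates 3 and 4. It was 262 and 310 without F-PRT replicates 3 and 4 and 55 with the block over all groups.

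**Figure D3:**
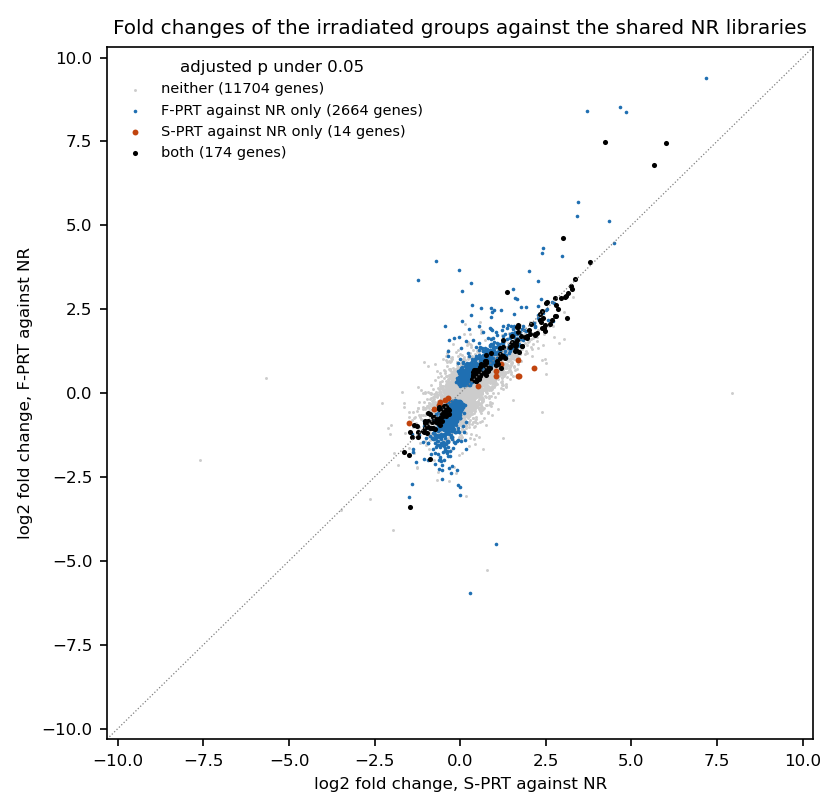
Log2 fold change of each of 14556 genes after F-PRT (vertical axis) against that after S-PRT (horizontal axis), both relative to the same 4 NR libraries, with genes marked by the comparison that called them. The 174 genes called in both lie in the same direction on both axes.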

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

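The tests of explanations and other splits here were all chosen after the results were seen. Among 322 groups of 4 libraries tested for named genes and list scores, 11 had a library whose gap to its nearest neighbour took most of the group's range, and chance gives about 1 in 20 such groups. In NR replicate 2, Adnp was at 12 CPM (7.41 to 7.97 in the other 3), Gsn at 542 CPM (999 to 1040), Ppara at 21.1 CPM (17.0 to 17.6) and Ptprb at 69.1 CPM (61.2 to 62.0). In NR replicate 1 Ahr was at 3.78 CPM (5.13 to 5.33), and in NR replicate 4 the circadian clock score was -0.0917 (0.0214 to 0.0429). In S-PRT replicate 2 Aqp7 was at 6.55 CPM (3.60 to 3.91) and Tek at 20.6 CPM (15.8 to 16.2). In S-PRT replicate 3 Col4a3 was at 3.41 CPM (2.14 to 2.33) and Gpx1 at 58.9 CPM (46.1 to 48.1), and in S-PRT replicate 4 Ppara was at 14.6 CPM (11.6 to 11.8).

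Camera's test of F-PRT against S-PRT, which addresses the difference between the modes directly, called 8 lists at the preset correlation of 0.01. Adjusted p was 3.4e-08 for collagens and fibrotic matrix, 2.1e-06 for basement membrane, 9.9e-05 for fibroblast identity markers, and 3e-05 for mitochondrially encoded mRNAs. It was 0.01 for TGF-beta signalling and calcium handling and 0.039 for complement, all 7 lower in F-PRT. It was 2.7e-05 for nuclear oxidative phosphorylation, higher in F-PRT, and 0.88 for each of the 8 with an estimated correlation.

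A first pattern is that 2841 genes passed in F-PRT against NR and 188 in S-PRT against NR. A trend on transcript length is argued against as the whole cause, because with it removed in the same fit the F-PRT count was 16.3 times the S-PRT count (587 and 36). Fitted on the groups compared alone, the counts were 557 for S-PRT and 2060 for F-PRT against NR, and with the replicate block on S-PRT and NR 1371 (831 with the trend removed). With replicates 1 and 2 against 3 and 4 as a term the S-PRT count was 2176. That split was read from these libraries and lies in the block too, so both higher counts were built in and the part of this spread stays open. A larger response to F-PRT stays open, with a difference in response size of 0.112 (exact permutation p = 0.314) that fell to -0.001 without F-PRT replicate 2.

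A second pattern is that log2 fold changes fall with transcript length across genes (Spearman rho -0.38 in S-PRT against NR and -0.55 in F-PRT against NR). Library depth is argued against as the whole cause for S-PRT, since the trend separated S-PRT from NR (exact permutation p = 0.029) while the totals were 31.2 ± 7.2 and 31.1 ± 4.5 M counts (SD, n = 4 each), and for F-PRT (24.3 ± 4.0 M counts, n = 3) it stays open. Across the 7 irradiated libraries the trend had r = -0.18 and rho = -0.04 with mean fragment length (permutation p = 0.73 and 0.96) and r = 0.63 and rho = 0.46 with library total (0.13 and 0.3), and without the 2 libraries farthest from the median r was 0.65 and 0.31. Over these and the same relations across all 11 libraries, which also differ by group, the smallest of 4 adjusted p was 0.26 for r and 0.22 for rho. Shorter fragments in irradiated libraries could give such a trend, and mean fragment length, read from length minus effective length, was 230 ± 2.9 bases in NR, 216 ± 15 in S-PRT and 217 ± 8.3 in F-PRT (SD, n = 4, 4 and 3, exact permutation p against NR = 0.14 and 0.029), so its part cannot be told apart from that of irradiation with so few libraries.

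Another pattern is that matrix genes were lower in F-PRT than in S-PRT. The length trend is argued against as the whole cause, since the collagen median was -0.47 with it removed (lowest of 10000 random lists of 35 genes -0.15). The spread between libraries of a group could give the difference (exact permutation p of the score 0.29). The 13 fibroblast identity markers outside the matrix list had a median of -0.39 (lowest of 10000 random lists -0.33, which does not test the groups). The score of all 15 had exact permutation p = 0.2. A lower share of fibroblast RNA in F-PRT and the dose rate itself stay open.

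Other splits of the libraries were run for each count. For S-PRT against NR the real split gave 188 genes and the highest of the other 34 gave 0 (1 of 35, the lowest share possible) over splits that ignore the pairing. Only 8 splits part all 4 same-numbered pairs, too few for a share under 0.05, and the 7 others of these gave 0 genes, and at most 732 with an unadjusted p under 0.05 against 2666 for the real split. The remaining splits reached 2032, with replicates 3 and 4 of both groups against 1 and 2. For F-PRT against NR the counts were 2841 and 7 at most (also 1 of 35), and neither share, unadjusted, excludes chance. For F-PRT against S-PRT edgeR called 0 genes, which all 35 splits reach whatever the data, so they decide nothing. The highest, 466, had S-PRT replicates 3 and 4 and F-PRT replicate 2 against the rest, which points to a structure of the samples. Genes with an unadjusted p under 0.05 numbered 2315 (3 of 35 splits as many, highest other 2904), and the DESeq2 Wald test called 167. For irradiated against NR 2 of 100 drawn splits, which ignore the pairing, gave 1000 or more, the real one included. The other, S-PRT 3 and 4 and F-PRT 2 and 4 against the rest, gave 1092, which points to a structure of the samples and leaves chance open. With the replicate block the real count was 320. For the number of lists called by camera chance cannot be excluded. There were 22 lists for S-PRT against NR (9 of 35 splits as many, highest other 27) and 14 for F-PRT against NR (18 of 35, highest other 25). There were 8 for F-PRT against S-PRT (28 of 35, highest other 29).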

How the results depend on the processing

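The fits with a robust dispersion, 1 surrogate variable, trends on length and GC content removed, parts of the replicates, or the block or split on S-PRT and NR alone were chosen after the data were seen. Directions held in all alternatives for the named genes that passed. Of 1363 values for 44 genes in S-PRT against NR, 967 kept the call, 396 lost it and 0 changed sign. Of 1767 values for 68 genes in F-PRT against NR, 1399 kept it, 368 lost it and 0 changed sign. Among genes that did not pass, Mdm2 in S-PRT against NR was -0.06 on log2(TPM + 1), and Col1a1 in S-PRT against NR was -0.19 with 1 surrogate variable and -0.02 (without NR replicate 2, and without S-PRT replicate 3) to 0.43 with a library left out. Where a count moved, the cause was not tested unless fewer genes or libraries entered the fit.

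For S-PRT against NR (188 genes) the counts were 14 with library size only, 605 with no filter, 697 with the DESeq2 Wald test, 2 with limma on log2(TPM + 1) and 891 with voom. They were 463 with 1 surrogate variable, 36 with the length trend removed (28 higher and 8 lower), 50 with length and GC trends removed and 557 with only the groups compared. For F-PRT against NR (2841) they were 134 with library size only, 71 on log2(TPM + 1), 587 with the length trend removed and 517 with length and GC trends removed. For F-PRT against S-PRT (0) they were 3 with DESeq2 size factors, 3 without mitochondrially encoded genes, 71 with no filter and 3 with the stricter filter. They were 167 with the DESeq2 Wald test (which gave no adjusted p for 5926 genes), 9 on log2(TPM + 1), 3 with a robust dispersion and 7 with 1 surrogate variable. For irradiated against NR (1000) they were 125 with library size only, 1860 with the DESeq2 Wald test, 7 on log2(TPM + 1) and 2511 with voom. They were 239 with the length trend removed (119 higher and 120 lower) and 261 with length and GC trends removed. For the overlap of calls (174) they were 14, 441, 535, 2 and 691 with library size only, no filter, the DESeq2 Wald test, log2(TPM + 1) and voom. They were 419, 28, 36 and 388 with 1 surrogate variable, the length trend removed, both trends removed and only the groups compared. The correlation of fold changes (0.734) was 0.634 with no filter. Lists called for F-PRT against S-PRT (8) numbered 16 with library size only and 13 with no filter. Over all alternatives and left-out libraries, 12 of 22, 4 of 14 and 4 of 8 list calls were kept in S-PRT against NR, F-PRT against NR and F-PRT against S-PRT. Of 15, 23 and 29 lists not called, 10, 11 and 17 were called in at least 1 of these settings. With an estimated correlation 0 lists were called in each of the 3 comparisons, and fry called 1, 3 and 0. The response size difference (0.112) was 0.316 on genes called in F-PRT against NR (exact permutation p = 0.029), a choice of genes that uses the F-PRT libraries, and 0.005 on genes called in S-PRT against NR (exact permutation p = 1).

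With library size only, the median of all genes moved to -0.136 in S-PRT against NR and 0.188 in F-PRT against S-PRT, and on log2(TPM + 1) to -0.132 and 0.126. Library size alone gave 78.6% higher calls in S-PRT against NR (67.6% with TMM) and 59 higher and 66 lower calls for irradiated against NR (620 and 380 with TMM). On log2(TPM + 1), 1 call was higher and 1 lower in S-PRT against NR (127 and 61 with TMM), and 9 were higher and 0 lower in F-PRT against S-PRT. The replicate block over all groups gave 60 genes for S-PRT against NR, 1501 for F-PRT against NR, 0 for F-PRT against S-PRT, 320 for irradiated against NR and an overlap of 55. F-PRT numbers did not pair with NR (correlations -0.45 to 0.23, 1 of 6 libraries closest to its own number) or S-PRT (-0.39 to -0.16, 0 of 6). Under that block camera no longer called epicardial and mesothelial markers in S-PRT against NR (adjusted p = 0.079). Besides collagens, interferon response and macrophage markers it called matrix proteases (0.0044) and immediate early genes (0.001) lower in F-PRT against S-PRT, and erythroid markers lower in F-PRT against NR. On S-PRT and NR alone, 1371 genes passed with the replicate block, 831 with the block and the length trend removed, 2176 with replicates 1 and 2 against 3 and 4 as a term, 1588 in replicates 1 and 2 and 1338 in replicates 3 and 4. There the block changed no list call but that of erythroid markers among the 34 lists tested.

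Leaving out each library in turn gave 26 to 444 genes for S-PRT against NR, 1382 to 3784 for F-PRT against NR, 0 to 103 for F-PRT against S-PRT, and 186 to 1584 for irradiated against NR. It gave an overlap of 26 to 310, a correlation of 0.622 to 0.756, a response size difference of -0.001 to 0.193, and 20 to 24, 10 to 19 and 5 to 20 lists in the 3 comparisons. The lowest and highest were without NR replicate 4 and F-PRT replicate 4 for S-PRT against NR and the overlap, and without F-PRT replicates 4 and 3 for F-PRT against NR. What depth alone limits was not tested. At these depths, spreads and group sizes, simulated 1.5-fold changes were recovered in 49.3%, 29.9% and 28.4% of cases in the 3 comparisons and 52.2% for irradiated against NR.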

Other observations

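The comparison of replicates 1 and 2 with 3 and 4 and the fits with the length trend removed, 1 surrogate variable, or S-PRT and NR alone were chosen after the data were seen, and the gene lists were fixed before. Clock genes were called lower after S-PRT (adjusted p = 7.8e-05, and adjusted p = 0.37 with an estimated correlation), with a median log2 fold change of -0.26 over 16 genes, of which 0 passed over all genes and 3 fell when adjusted over the list alone. The repressor Bhlhe41 had -0.38 ± 0.09, adjusted p = 0.059 and the nuclear receptor Nr1d1 -0.43 ± 0.13, adjusted p = 0.11. After F-PRT their median was -0.19 and the list was not called (adjusted p = 0.078, but 0.014 with no filter, 0.033 without NR 4 and 0.026 without F-PRT 3). In that list Clock (-0.42 ± 0.11, adjusted p = 0.023) and Bhlhe41 (-0.33 ± 0.10, adjusted p = 0.035) fell, and the expected counts of Bhlhe41 and Nr1d1 were not whole in any of 11 libraries. B and plasma cell markers were called lower after S-PRT (adjusted p = 0.0019, and adjusted p = 0.39 with an estimated correlation), with a median of -0.53. Of 11 members 0 passed over all genes and 3 fell when adjusted over the list alone. They were not called after F-PRT (median -0.53, adjusted p = 0.23), but were with the length trend removed (0.023). Epicardial and mesothelial markers had a median of -2.02 over 5 genes after S-PRT (adjusted p = 0.049, and adjusted p = 0.49 with an estimated correlation), with 0 past the test over all genes and 2 lower when adjusted over the list alone. The call was lost without S-PRT replicate 1 (adjusted p = 0.1), without S-PRT replicate 4 (0.11), with DESeq2 size factors (0.054), with library size only (0.068), with the replicate block over all groups (0.079) and with the length trend removed (0.063). Their score was -0.97, -1.20, 0.99 and 1.17 in NR replicates 1 to 4 and -1.06 ± 0.30 in S-PRT (SD, n = 4, exact permutation p = 0.26). After F-PRT the median was -0.94 and the list was not called (adjusted p = 0.27). Erythroid markers had negative log2 fold changes against NR in all 6 cases, with medians of -0.54 after S-PRT (adjusted p = 0.075) and -0.43 after F-PRT (0.13), and were not called. They were called lower after S-PRT in 12 of 23 other settings, among them the paired fit of S-PRT and NR alone (adjusted p = 0.0072), and after F-PRT in 4 of 20 (lowest 5.4e-05 without F-PRT 4).

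Lists of other cell types and tissues that could lie in the tissue piece were not called in either comparison with NR, though pericyte and Schwann cell markers were called lower after S-PRT with 1 surrogate variable (adjusted p = 0.037 for each). So were Schwann cell markers without NR 2 (0.027), while T and NK cell markers were called higher without S-PRT 1 (0.012). Median log2 fold changes after S-PRT and F-PRT were 0.53 and -0.08 for T and NK cell markers (adjusted p = 0.29 and 0.91), -1.18 and 0.17 for mast cell markers (adjusted p = 0.35 and 0.76) and -0.07 and -0.34 for lymphatic endothelial markers (adjusted p = 0.74 and 0.27). They were 0.04 and 0.00 for pericyte and smooth muscle markers (adjusted p = 0.69 and 0.46), -0.16 and -0.08 for Schwann cell and nerve markers (adjusted p = 0.14 and 0.55) and 0.29 and 0.32 for atrial markers (adjusted p = 0.42 and 0.19), the last of which fry called higher after F-PRT (adjusted p = 0.038). After F-PRT the atrial myosin light chain Myl4 (1.01 ± 0.25, adjusted p = 0.019) and the intermediate filament gene Des (0.33 ± 0.10, adjusted p = 0.04) rose. The lymphatic transcription factor Prox1 (-0.57 ± 0.14, adjusted p = 0.017) and the potassium channel subunit Abcc9 of pericytes (-0.81 ± 0.16, adjusted p = 0.0098) fell, and no other member of these 6 lists passed in either comparison. Camera's direction was lower for pericyte and smooth muscle markers after both modes, where mean log2 fold changes were 0.18 and 0.04. It was lower for mast cell markers after F-PRT (mean -0.02, median 0.17) and higher for T and NK cell markers (mean 0.11, median -0.08). Lists with fewer than 5 tested members were not tested as lists. Their medians were 1.30 and 0.78 for 4 neutrophil markers, 0.39 and 0.64 for 4 skeletal muscle markers, -0.52 and -0.42 for 2 adipocyte markers, -0.02 and -0.17 for 4 sex-linked genes and 0.86 and 0.62 for 1 lung epithelial gene. No member of these passed over all genes, and when adjusted over the list alone 3 neutrophil markers were higher after S-PRT and 1 adipocyte marker was lower after each mode. No list of these 2 paragraphs was called in F-PRT against S-PRT, but with the length trend removed clock genes were called higher (adjusted p = 0.018), and without F-PRT 4 lymphatic endothelial (0.0075), pericyte and smooth muscle (0.018) and erythroid markers (0.00014) were called lower.

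S-PRT against NR was also fitted apart in replicates 1 and 2 and in replicates 3 and 4, on 13760 genes tested in both parts. These fits called 1581 and 1244 genes, of which 278 were higher and 122 lower in both and 5 went in opposite directions, beside 51.4 and 22.1 for independent lists. The log2 fold changes correlated across genes with r = 0.521. The parts share no library, and the correlation of fold change with transcript length was -0.47 in replicates 1 and 2 and -0.20 in replicates 3 and 4.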
